A study of Homo sapiens with 4 samples.

How the data were processed

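RNA was extracted with TRIzol from H9 cells in mTeSR, and libraries were made from 3 ug of total RNA with a NEBNext Ultra Directional kit, which marks strand, per the labels' protocols. The strand setting used in counting is not given in the sources used here, so values of antisense and overlapping genes are uncertain. The authors deposited 1 table per library with 1 estimated count per gene for 58219 gene identifiers. The deposited values are estimated counts (expected counts) that need not be whole, to judge from the values: 66.7%, 66.7%, 67.1% and 69.0% lay within 1e-9 of a whole number, and library totals differed. HISAT2 and StringTie are listed for build hg38, per the submitters' processing notes, with no version, order or role. The counting tool, the annotation and any treatment of reads that match several genes are not given in the sources used here. No normalization by the authors was seen in the values. Transcript or exon values were not analysed here.

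Gene names, types, coordinates, GC content and exon numbers were taken from GENCODE 29 (GRCh38) by stable Ensembl identifier: 57836 of the identifiers matched, 55008 with the same version, and 45 belonged to the pseudoautosomal region of chromosome Y. Exon numbers are those of the annotated transcript with the most exons. Genes on chromosome Y and XIST were left out of the genes named.

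Estimated counts were rounded to whole numbers, which gave totals of 29716013 (NT, 24 h), 28269605 (P8i-3, 24 h), 29525592 (NT, 48 h) and 28662126 (P8i-3, 48 h). Counts were scaled with TMM factors in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), which lay between 0.999 and 1.002 over all genes. For each time the log2 difference P8i-3 minus NT was taken on log2(CPM + 1), so it understates the change of low genes. Genes with a mean of at least 1 CPM over the 4 libraries, 15708 in all, were counted as higher or lower at an absolute log2 difference of at least 1. NT at 48 h against NT at 24 h, counted the same way, served as background. The median log2 difference over all tested genes was -0.03 at 24 h, -0.07 at 48 h and -0.01 between the NT libraries. Folds are ratios of scaled CPM with exact 95% intervals from the counts of the 2 libraries. Such intervals, and the floor of 3 counts per library that a count of 0 allows, cover counting error only, since the reads carry no molecular identifiers in the values used here.

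The knockdown was tested over both times with edgeR's quasi-likelihood test, with terms for the time label and the knockdown, which leaves 1 residual degree of freedom, and Benjamini-Hochberg adjustment with a threshold of 0.05. This fit took its TMM factors from the genes tested (0.973 to 1.02), and its log2 values exceed the mean of both single-time differences by a median of 0.05 among genes with a mean of at least 5 CPM. In the report, log2 values described as having risen, fallen or not passed come from this fit. The test and size rule were tested on simulated counts for 15541 genes, with the dispersion of this fit and 1 common value for all genes. Each changed gene got the same change at both times, few genes were changed, and the time label had no effect. The simulated rates of recovery and error thus need not hold for these libraries. The edgeR test recovered 69.4% of 98 genes changed 2-fold and 100% of 96 genes changed 4-fold, and 5.20% of its 173 calls were unchanged genes. DESeq2 1.42.0 recovered 42.9% and 90.6%, with 1.53% of 131 calls unchanged.

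The lists were 28 sets of genes written by hand, among them p53 targets, genes promoting and opposing apoptosis, pluripotency, ectoderm, mesoderm, endoderm, trophoblast or amnion and fibroblast markers, the U5 particle and tri-snRNP, other spliceosome genes, SR and hnRNP proteins, G1/S, G2 and mitosis, DNA repair, integrated and endoplasmic reticulum stress, heat shock, interferon response, immediate early genes, nonsense-mediated decay factors, glycolysis and hypoxia, cholesterol synthesis, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, replication-dependent histones, TGF-beta and matrix, and Wnt, FGF and nodal signalling. A list's median was placed among 10000 random lists of the same size drawn within 20 classes of mean expression, and its interval came from 2000 bootstrap draws of its members. Lists with fewer than 5 measured members got neither. Some genes stand on more than 1 list.

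The genes named were fixed by a rule. PRPF8 and RCHY1 were always named, and 1 of the lists and some genes under the rule are not reported here. At each time, the 10 protein-coding genes with the largest positive and the 10 with the largest negative log2 difference were named among those with a mean of at least 5 CPM and an absolute difference of at least 0.5 in the same direction at the other time. Up to 4 members per list with the largest mean difference, and the 5 genes with the smallest p of the knockdown in each direction, completed the rule. List members named beyond these 4 were chosen after their values were seen. The groups, tests, lists, naming rule and the first set of alternatives were set before the data were examined. Alternatives covered the pseudocount, the filter on low counts, median ratio scaling, protein-coding genes alone, a 1.5-fold size, DESeq2 in place of edgeR, no time term, and each library left out in turn together with the time term. A fit with a library left out takes its spread from the 24 h and 48 h libraries of the group that keeps both. Removing a lowess trend on GC content (span 0.3) and random lists also matched on GC content and exon number were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6).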

Results

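Gene expression was profiled by RNA sequencing in H9 cells, an established human embryonic stem cell line, kept in mTeSR, a feeder-free medium for pluripotent cells. The labels named control cells NT, with a wild-type genotype, and cells with a knockdown of PRPF8 named P8i-3. PRPF8 encodes the large protein at the centre of the U5 small nuclear ribonucleoprotein, which holds the catalytic core of the spliceosome. Each of the 4 groups, NT and P8i-3 at 24 h and at 48 h, was 1 library, so no difference at a single time had a replicate check and none was given a p-value. What the 24 h and 48 h were counted from was not stated in the labels. The libraries held 29716013 (NT, 24 h), 28269605 (P8i-3, 24 h), 29525592 (NT, 48 h) and 28662126 (P8i-3, 48 h) gene counts. At this depth a count of 0 allowed a level of up to 0.101, 0.106, 0.102 and 0.105 CPM (counts scaled to the library total), in the same order. Genes above 0 numbered 29581, 29649, 29381 and 27859, so the P8i-3 library at 48 h listed the fewest. Genes with at least 10 counts numbered 19233, 19426, 19212 and 19896, the most in that same library. Mitochondrially encoded genes took 4.66%, 5.31%, 4.64% and 6.19% of the counts, a larger share in the P8i-3 library at each time.

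**Figure D1:**
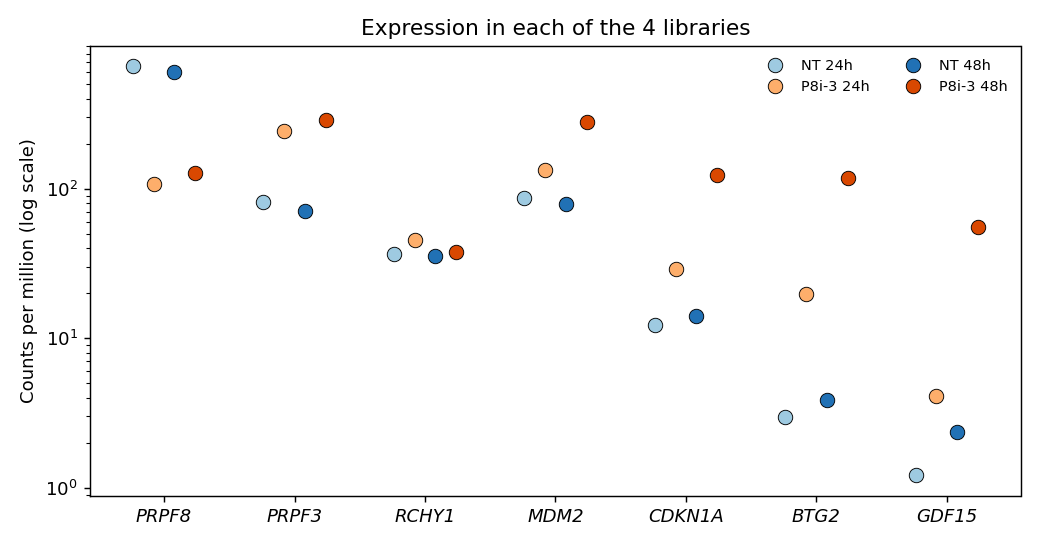
Level of 7 genes (x axis) in CPM (y axis, log scale), where each point is 1 library, the only one of its group, and no error is drawn. PRPF8 was lower in both P8i-3 libraries than in the NT library of the same time, RCHY1 stayed between 35.5 and 45.2 CPM, and CDKN1A reached 124 CPM in the P8i-3 library at 48 h.

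The first comparison checked the knockdown itself. PRPF8 (ENSG00000174231.16, chromosome 17, 1650629 to 1684882, minus strand, GRCh38) was measured at 657 CPM in NT and 108 CPM in P8i-3 cells at 24 h. At 48 h it was measured at 602 and 127 CPM. P8i-3 cells thus held 0.164 times the NT level at 24 h (95% counting interval 0.158 to 0.170) and 0.210 times at 48 h (0.203 to 0.218). On the log2 scale PRPF8 was lower by values of -2.60 and -2.24, against -0.13 between the 2 NT libraries. It fell in the test over both times, with a log2 difference of -2.38 (SE 0.15, adjusted p = 2.81e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), in the direction that the labels give. The values were sums over each gene, so the fold covers all PRPF8 transcripts together.

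The series title names PIRH2, the product of RCHY1, a ubiquitin ligase that targets p53 for degradation, and asks about its splicing and the p53 pathway. The total RNA of RCHY1 (ENSG00000163743.13, chromosome 4, 75479037 to 75514764, minus strand, GRCh38) differed little between the groups, with 36.5 CPM in NT and 45.2 CPM in P8i-3 cells at 24 h, and 35.5 and 37.9 CPM at 48 h. Its log2 differences were 0.30 and 0.09, and it did not pass the test over both times (log2 0.25, SE 0.18, adjusted p = 0.323, edgeR). Transcripts and exons of RCHY1 were not analysed here, so its splicing is not addressed. Among other ubiquitin ligase genes, MDM2 (log2 1.27), the main p53 ligase and itself a p53 target, and MDM4 (0.68), its partner, rose over both times. COP1 (-0.62), HUWE1 (-0.58) and STUB1 (-1.08) fell. MDM2 did not pass with DESeq2 (adjusted p = 0.127). None of these genes passed in the fit without the NT library at 48 h, which, like each fit with a library left out, also had no term for time.

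At 24 h the P8i-3 cells had higher RNA of genes that p53 is known to switch on and of splicing partners of PRPF8. BTG2, an antiproliferative p53 target, was 6.68-fold higher (95% counting interval 5.33 to 8.46). PRPF3, a protein of the U4/U6 particle that joins U5 in the tri-snRNP, was 3.01-fold higher (2.87 to 3.15). SYT4, a synaptotagmin of neurons, was 3.71-fold higher (3.08 to 4.48) and FOSL1, a subunit of the AP-1 transcription factor, 2.89-fold higher (2.48 to 3.38). LOXL2, which crosslinks collagen, was measured at 0.179 times the NT level (0.154 to 0.207).

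The other protein-coding genes with the largest positive log2 differences at 24 h were GLIPR1 (1.61), NEFH (1.42, a neurofilament subunit), SLX1A (1.36), TNFRSF10C (1.27, a decoy receptor for the death ligand TRAIL), LCP1 (1.27, an actin-bundling protein) and TXNIP (1.27, an inhibitor of thioredoxin). The largest negative ones after PRPF8 and LOXL2 were SLX1B (-1.88), TTYH2 (-1.82), B9D1 (-1.63, of the ciliary transition zone), CRTC1 (-1.61, a coactivator of CREB), ATP6V1G2-DDX39B (-1.58), MRM1 (-1.58), MMP25 (-1.57, a membrane-bound metalloproteinase) and GALK1 (-1.52, galactokinase). SLX1A and SLX1B are nearly identical copies of the same nuclease gene, moved in opposite directions and share reads, so both values are uncertain. ATP6V1G2-DDX39B is a readthrough transcript that overlaps DDX39B, and its value is uncertain for the same reason. Among 15708 genes with a mean of at least 1 CPM, 118 were higher and 277 lower by an absolute log2 difference of at least 1 in P8i-3 cells at 24 h, so 29.9% of the 395 were higher. With the trend on GC content removed, an alternative chosen after seeing the data, 122 were higher and 172 lower, and 41.5% were higher.

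At 48 h p53 targets stood further above the control than at 24 h, and the genes far below it included genes with many exons. BTG2 was 30.3-fold higher (95% counting interval 25.2 to 36.9) and GDF15, a secreted stress cytokine and p53 target, 23.5-fold higher (18.5 to 30.3). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, went from 14.2 CPM in NT to 124 CPM in P8i-3 cells, an 8.77-fold difference (7.92 to 9.73). The death receptor gene FAS was 7.62-fold higher (6.13 to 9.57). PLCB3, a phospholipase C with up to 32 annotated exons, was at 0.125 times the NT level (0.116 to 0.135), and NBEAL2, needed for platelet granules and with up to 54 exons, at 0.120 times (0.106 to 0.135).

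The other protein-coding genes with the largest positive log2 differences at 48 h were FOSL1 (3.17), VGF (2.80, a neuropeptide precursor), SYT4 (2.47), NUAK2 (2.44, a kinase related to AMPK), PHLDA3 (2.40, a p53 target that opposes AKT) and CSF1 (2.33, a macrophage growth factor). The largest negative values belonged to SLX1B (-3.47, uncertain as above), PGGHG (-3.17), OPLAH (-3.14, 5-oxoprolinase), EML3 (-3.05, a microtubule-binding protein), NRBP2 (-2.97), B9D1 (-2.85), ACADVL (-2.77, of mitochondrial fatty acid oxidation) and FBN3 (-2.77, a fibrillin). The genes named in this paragraph and the preceding one passed the test over both times in edgeR, but CDKN1A, NBEAL2, VGF, NUAK2, PGGHG, OPLAH, EML3, NRBP2 and ACADVL did not pass with DESeq2. Without the NT library at 48 h and without a time term only 10 genes rose and 18 fell of all those tested in edgeR. In total 607 genes were higher and 1395 lower by an absolute log2 difference of at least 1 at 48 h, so 30.3% of the 2002 were higher.

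Genes with many exons stood lower than genes with few at 48 h. The median log2 difference of protein-coding genes was 0.22 for the 215 genes with 1 exon, 0.06 for 2900 genes with 2 to 5 exons, -0.07 for 6834 genes with 6 to 15 exons and -0.33 for 3433 genes with at least 16 exons. The share of genes lower by at least 1 was 1.86%, 4.83%, 8.94% and 15.8% across these classes at 48 h, and 0.930%, 0.966%, 1.80% and 2.71% at 24 h. The 1297 lower protein-coding genes at 48 h had a median GC content of 56.4%, against 47.8% for the other 12085, and a median of 14 exons in their largest transcript against 9.

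**Figure D2:**
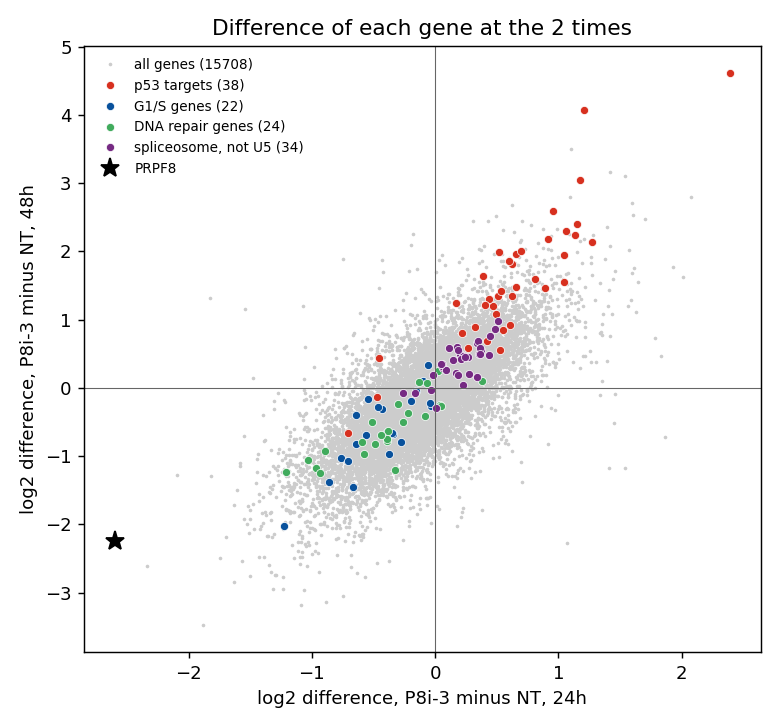
Log2 difference P8i-3 minus NT at 24 h (x axis) and at 48 h (y axis) for the 15708 genes tested, 1 grey point per gene and 1 library per group, with PRPF8 as a star and members of 4 lists (p53 targets, G1/S, DNA repair and spliceosome genes other than U5) in colour. The differences at both times run together (Pearson's r = 0.73 across genes), with BTG2 at 2.39 and 4.61 in the upper right corner.

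The 2 NT libraries gave the background for a difference between single libraries. VGF was lower in NT cells at 48 h than at 24 h (-1.22), while SYT4 (0.01) and CDKN1A (0.19) differed little. Between NT at 48 h and NT at 24 h, 53 genes were higher and 37 lower by the same size, 90 in all, against 395 and 2002 for P8i-3 against NT. In simulated counts, with 1 spread for all genes estimated from these libraries, 26 of 15347 unchanged genes reached the size at 24 h, 22 at 48 h and 0 in the same direction at both. These numbers lie below the 90 between the NT libraries, so the simulation may understate the spread between libraries.

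Differences at 24 h and 48 h, which share no library, ran in the same direction for most genes. BTG2, FOSL1, SYT4, GDF15 and CDKN1A were higher by at least 1 at both times, and PRPF8, LOXL2, PLCB3 and NBEAL2 lower. In all, 77 genes were higher at both times, where independent lists would share 4.56, and 211 were lower at both, where independent lists would share 24.6. A set of 6 genes went in opposite directions. With the trend on GC content removed, an alternative chosen after seeing the data, 83 genes were higher and 126 lower at both times. Both times compared knockdown with control cells, so a lasting difference between these cells with another cause would also give shared genes. The overlap therefore cannot assign the shared genes to the loss of PRPF8. Of the genes higher at 48 h, 93.9% had a positive difference at 24 h, and of those lower at 48 h, 96.5% had a negative one. Across genes, which are not independent replicates, Pearson's r was 0.73 and Spearman's rho 0.73. Of the 118 genes higher at 24 h, 63 had a larger difference at 48 h, as had 180 of the 277 lower genes, a change of the difference that has no replicate check.

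Most listed genes controlled by p53 were higher in P8i-3 cells. Of 38 listed p53 targets, all measured, 35 rose over both times, XPC fell (-0.65) and 2 did not pass, namely DDB2 (log2 -0.27) and TP53I3 (0.04), and the counts adjusted over the list alone were the same (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). XPC and DDB2 both encode proteins that recognise DNA damage for nucleotide excision repair. The largest fitted log2 changes were those of BTG2 (3.94, SE 0.35, adjusted p = 2.72e-06), GDF15 (3.44, SE 0.44, adjusted p = 8.85e-05), CDKN1A (2.25, SE 0.30, adjusted p = 0.000112) and TNFRSF10C (2.06, SE 0.30, adjusted p = 0.000197), each higher in both P8i-3 libraries. With DESeq2 30 of the list rose, and CDKN1A did not pass (adjusted p = 0.0597). The median log2 difference of the list was 0.60 at 24 h (95% bootstrap interval over members 0.51 to 0.74) and 1.48 at 48 h (1.24 to 1.90), against 0.06 between the NT libraries, at percentile 99.1. The medians at 24 h and 48 h lay at percentile 100 of 10000 random lists matched on expression, which describes these libraries, and 35 of the 38 members differed more at 48 h than at 24 h, a change that was not tested. The number that rose was 20 with all libraries and no term for time. Far fewer rose without either NT library, in fits where the change between the P8i-3 libraries counted as spread. Without either P8i-3 library most of the list still rose.

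Genes that promote apoptosis rose in part. Of 19 measured members 8 rose, 1 fell and 10 did not pass, with the same counts adjusted over the list alone. FAS (log2 2.05), TNFRSF10A (1.32) and TNFRSF10B (1.26) encode death receptors, and HRK (1.51), BBC3 (1.13), BAX (0.84) and PMAIP1 (0.61) encode proteins of the mitochondrial pathway. Most of the risers, among them FAS, TNFRSF10B, BBC3, BAX and PMAIP1, were also on the list of p53 targets. BMF, which encodes another BH3-only protein, fell (-0.66) in edgeR, a call that was lost with DESeq2 (adjusted p = 0.0824), with median ratio scaling and without a time term, where 5 genes rose. Medians of the list were 0.26 at 24 h and 0.39 at 48 h, at percentiles 99.9 and 99.9, against 0.09 between the NT libraries at percentile 96.5. Of 8 measured genes that oppose apoptosis 0 passed the edgeR test, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 with DESeq2. MCL1 had a log2 value of -0.02 and BCL2L1 of 0.23. Without the NT library at 48 h none of the promoting genes passed, and 2 did without the NT library at 24 h, while 2 opposing genes rose without the P8i-3 library at 24 h.

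Genes of DNA replication and repair were lower. Of 22 genes of the G1/S transition 12 fell and none rose, 15 when adjusted over the list alone. CDC45 (log2 -1.71), part of the replicative helicase, E2F1 (-1.12), the transcription factor that drives S phase entry, RRM2 (-1.02), a ribonucleotide reductase subunit, and CCNE1 (-0.87), cyclin E1, fell most. MCM2 (0.05) and TYMS (0.19) did not pass. Of 24 DNA repair genes 13 fell and none rose, 14 adjusted over the list alone, among them BLM (-1.20), a helicase, FANCA (-1.06), of the Fanconi anaemia complex, and XRCC3 (-1.03). Of 24 genes of G2 and mitosis 4 fell (CDC20, ESPL1, KIF20A and BUB1B) and 2 adjusted over the list alone (CDC20 and BUB1B did not pass with DESeq2), and MKI67, the proliferation marker, had a log2 value of -0.27 that did not pass. Medians at 24 h and 48 h were -0.41 and -0.66 for G1/S, -0.38 and -0.66 for repair, and -0.14 and -0.44 for G2 and mitosis, all at percentile 1.47 or lower, against -0.07, -0.05 and -0.06 between the NT libraries. These counts became 7, 8 and 0 with all libraries and no time term. Without either NT library few or none of these genes fell. Without either P8i-3 library the G1/S and repair genes fell in numbers near those of the main test, and hardly any rose. Of the G2 and mitosis genes 16 fell without the P8i-3 library at 24 h, and 1 rose and 1 fell without that at 48 h. Of 9 measured replication-dependent histone genes, which share reads among near-identical copies and are uncertain, 0 passed with edgeR, 0 adjusted over the list alone and 0 with DESeq2, and 1 had an unadjusted p under 0.05.

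Other components of the spliceosome were higher while PRPF8 was lower. Of 18 genes of the U5 particle and the tri-snRNP, 8 rose, PRPF8 alone fell and 9 did not pass, with the same counts adjusted over the list alone. PRPF3 rose most (log2 1.86, SE 0.15, adjusted p = 1.09e-06, edgeR), then PRPF6 (0.86) and PRPF4 (0.85), also of the tri-snRNP, and SNRNP200 (0.81), the helicase that unwinds U4 from U6. EFTUD2 (0.21), the U5 GTPase that binds PRPF8, did not pass. Of 34 other spliceosome genes 13 rose and none fell, 18 adjusted over the list alone, with RBM22 (0.80), BUD31 (0.73) and SF3B6 (0.66) as the largest. The medians at 24 h and 48 h were 0.17 and 0.40 for the first list and 0.21 and 0.43 for the second, against -0.04 and -0.07 between the NT libraries. Of 28 SR proteins, hnRNP proteins and their kinases 6 rose and 2 fell, 6 and 3 adjusted over the list alone, with PTBP2 (0.88) up and its paralog PTBP1 (-0.54) down. Of the 8, 13 and 6 risers, few or none passed without either NT library. Without either P8i-3 library at least as many of each list rose as in the main test, and more of the third list also fell. Without the P8i-3 library at 24 h, 25 of the second list rose and 1 fell, and 10 and 8 of the third.

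**Figure D3:**
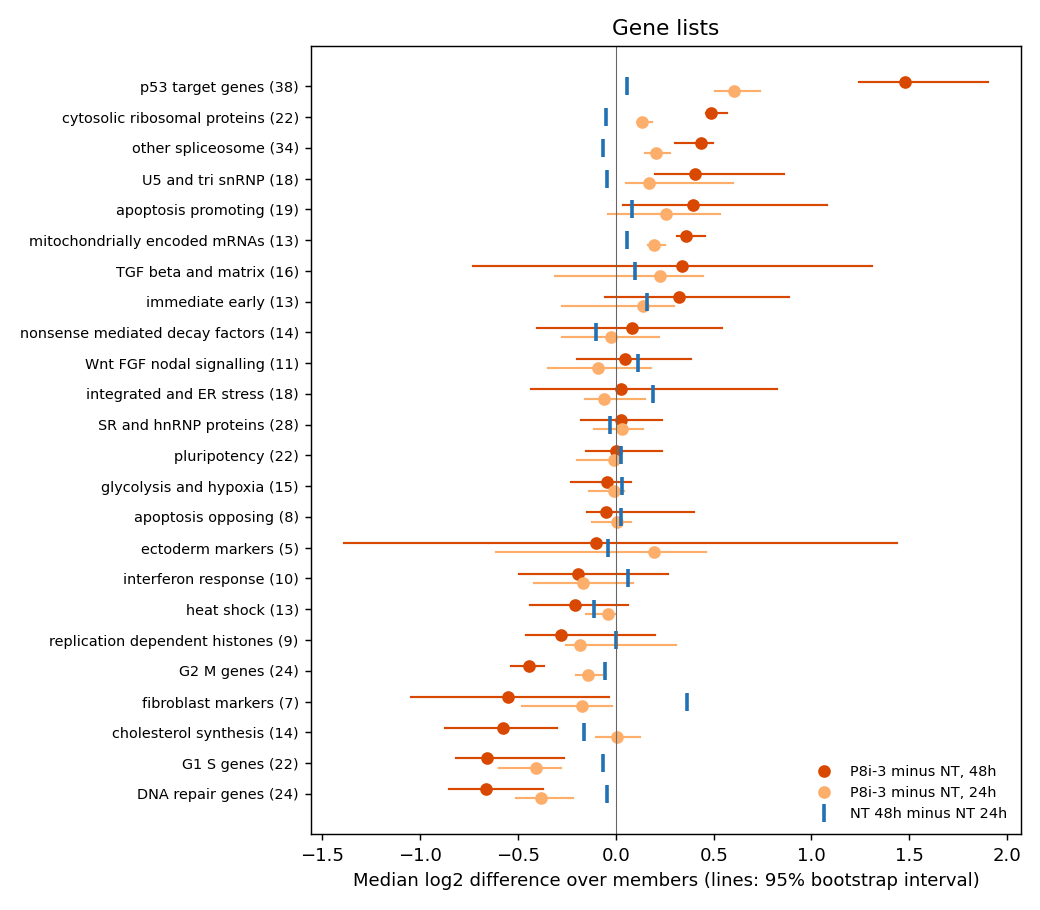
Median log2 difference over the members of 24 gene lists with at least 5 measured genes (x axis), for P8i-3 minus NT at 24 h and at 48 h (points, with 95% bootstrap intervals over members as lines) and for NT at 48 h minus NT at 24 h (vertical marks), with the number of measured genes in brackets. The p53 targets reach 0.60 and 1.48, and the G1/S and DNA repair genes lie at -0.66 at 48 h.

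The core pluripotency factors differed little. POU5F1 (log2 0.16), NANOG (0.13) and SOX2 (0.03) did not pass the test, where POU5F1 and NANOG share reads with pseudogenes and are uncertain. Of 22 measured pluripotency genes none rose and 3 fell, also adjusted over the list alone, namely DNMT3B (-0.80), a DNA methyltransferase, DPPA4 (-0.78) and TDGF1 (-0.60), a coreceptor of nodal. Medians of the list were -0.01 at 24 h and 0.00 at 48 h. Markers of differentiated cells were mostly below the expression limit. Of 5 measured ectoderm genes OTX2 rose (adjusted p = 0.00125, edgeR) and SOX10 (-1.98) fell, 0 of 4 mesoderm genes and 0 of 1 endoderm gene (AFP) passed with edgeR or DESeq2, with 2 and 0 at an unadjusted p under 0.05, and IGFBP3 (0.94) rose of 3 trophoblast or amnion genes. Adjusted over the list alone these counts were the same, except that KRT7 (-0.70) of the trophoblast list also fell. OTX2 (-0.73) and IGFBP3 (-1.19) were lower in NT cells at 48 h than at 24 h. IGFBP3 in P8i-3 cells at 48 h (11.8 CPM) lay below its NT level at 24 h (12.8 CPM). Of 7 fibroblast markers COL6A3 (-1.36) and THY1 (-0.47) fell, also adjusted over the list alone. Their median was -0.17 at 24 h and -0.55 at 48 h, and 0.36 between the NT libraries. COL6A3 did not pass with DESeq2 (adjusted p = 0.136), which gave no adjusted p for SOX10. Without the NT library at 48 h none of these genes passed, whereas of the pluripotency genes 6 rose and 5 fell without the P8i-3 library at 24 h, and 3 rose and 3 fell without that at 48 h, and of the mesoderm genes 1 rose and 2 fell without the P8i-3 library at 24 h.

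Stress genes divided. Of 18 genes of the integrated and endoplasmic reticulum stress responses 5 rose and 1 fell, 7 and 2 adjusted over the list alone. DDIT3 (log2 1.88), which encodes CHOP, ATF3 (1.11) and DDIT4 (1.10), an inhibitor of mTORC1, rose, and PSAT1 (-0.67), of serine synthesis, fell. HSPA5, the chaperone BiP, did not pass (-0.41), and the list median was -0.06 at 24 h, 0.03 at 48 h and 0.19 between the NT libraries. Of 13 heat shock genes HSPA4L (1.24) rose and HSPA8 (-0.48) and HSPA1A (-0.47) fell, 1 and 3 adjusted over the list alone, where HSPA1A and HSPA1B are near-identical and uncertain. Of 13 immediate early genes EGR1 (1.72), FOSB (1.70), ATF3 and JUN (0.66) rose, 4 also adjusted over the list alone. Of 10 interferon response genes 0 passed with edgeR, 0 adjusted over the list alone and 0 with DESeq2, and 1 had an unadjusted p under 0.05. Of 14 nonsense-mediated decay factors 4 rose, with MAGOH (0.61) first, and UPF2 (-0.55) fell, 5 and 4 adjusted over the list alone. With DESeq2 JUN (adjusted p = 0.121) and HSPA1A (0.111) did not pass and FOSB had no adjusted p, and the numbers that rose were 3 for the integrated stress genes, 2 for the immediate early genes and 2 for the decay factors. Of the decay factors 2 also rose with median ratio scaling, and 2 with no filter. With all libraries and no time term 1 integrated stress gene rose and 1 fell, and 1 decay factor rose and 1 fell. In that setting 1 heat shock gene rose and 0 fell, and 0 immediate early genes passed. None of the genes in these lists passed without the NT library at 48 h. Without the P8i-3 library at 24 h, 8 integrated stress genes rose and 3 fell, 5 heat shock genes fell, 6 immediate early genes rose, 1 interferon gene rose and 2 fell, and 5 decay factors rose and 5 fell. Without that at 48 h, 2 integrated stress genes rose and 2 fell, 1 heat shock gene fell and 0 immediate early genes passed.

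Matrix and cytoskeleton genes associated with TGF-beta signalling went both ways. Of 16 measured members 8 rose and 3 fell, 8 and 5 adjusted over the list alone. ACTA2 (log2 1.34), smooth muscle actin, and TAGLN (1.18), an actin-binding protein, were among those that rose, and ID3 (-0.79), ID1 (-0.73) and FN1 (-0.59), fibronectin, fell. TAGLN did not pass with DESeq2 (adjusted p = 0.257) and was lower in NT cells at 48 h than at 24 h (-1.14). Of 11 genes of Wnt, FGF and nodal signalling ETV5 (0.48) rose, but 0 passed adjusted over the list alone and 0 with DESeq2. Of 14 genes of cholesterol synthesis MVD (-0.79), LSS (-0.78) and IDI1 (-0.58), all enzymes of the pathway, fell, also adjusted over the list alone, and the median went from 0.01 at 24 h to -0.58 at 48 h, against -0.16 between the NT libraries. No cholesterol gene passed with DESeq2. Without the P8i-3 library at 24 h more of them fell. Without that at 48 h some rose and none fell. That fit sets P8i-3 cells at 24 h against both NT libraries, so the lower NT values at 48 h enter its difference. PFKP (-0.61), a phosphofructokinase, fell alone among 15 genes of glycolysis and hypoxia, also adjusted over the list alone. Without the NT library at 48 h none of these genes passed. With all libraries and no time term 2 matrix genes rose and 2 fell, and 0 of the cholesterol, glycolysis or Wnt, FGF and nodal genes passed. Without the P8i-3 library at 24 h 2 glycolysis genes rose and 3 fell. Without that at 48 h 4 matrix genes rose and 4 fell, and 1 Wnt, FGF and nodal gene rose and 4 fell.

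Ribosomal protein and mitochondrial messenger RNAs were slightly higher. Of 22 cytosolic ribosomal protein genes 9 rose and none fell, 18 adjusted over the list alone and 2 with DESeq2, with RPL22 (log2 0.67) and RPS19 (0.56) first. Their median was 0.13 at 24 h and 0.49 at 48 h, against -0.05 between the NT libraries, and processed pseudogenes share reads with them. Of 13 mitochondrially encoded mRNAs 5 rose and none fell, 6 adjusted over the list alone, 3 with DESeq2 and 3 with median ratio scaling, among them MT-ND6 (0.49) and MT-ND3 (0.47). Their medians of 0.20 and 0.36, against 0.06, lay at percentiles 99.4 and 98.4, but at 76.0 and 89.3 of random lists also matched on GC content and exon number, an alternative chosen after seeing the data. Median ratio scaling left 3 ribosomal protein genes. In both lists none passed without the NT library at 48 h, and none without the NT library at 24 h, while 21 and 13 rose without the P8i-3 library at 24 h and 8 and 10 without that at 48 h, and 1 and 0 with all libraries and no time term. Of the 25 lists with at least 5 measured members, 9 medians at 24 h and 12 at 48 h lay outside the central 95% of random lists, as did 7 between the NT libraries, where chance gives 1.25. These 7 were the lists of p53 targets, fibroblast markers, integrated stress, heat shock, nonsense-mediated decay, cholesterol synthesis and mitochondrial mRNAs.

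Over both times together, the genes with the smallest p-values in the test of the knockdown were PRPF8, LOXL2 (log2 -2.59), MYO19 (-1.58, a mitochondrial myosin), NT5DC2 (-1.61) and TAF15 (-1.28, an RNA-binding protein) among those that fell. BTG2, PRPF3, LINC00641 (1.70), AF127577.4 (4.22) and AC005538.2 led those that rose, the last 3 of them outside the protein-coding genes. AC005538.2 had 0 counts in both NT libraries, against 1.91 CPM and 7.62 CPM in P8i-3 cells, so its fold has only a lower limit, and it did not pass with DESeq2 (adjusted p = 0.117). In this test 1587 genes rose and 2097 fell of 15708 (adjusted p under 0.05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), while 22 rose and 7 fell with the time label. DESeq2 gave 864 and 1255, and the model without a time term 706 and 815. The model had 1 residual degree of freedom, so a gene's own spread is the departure of both times from a common difference. edgeR combined it with the spread shared over all genes, which counted as 18.2 prior degrees of freedom. The p-values thus rest mostly on that shared spread. They measure only the spread between these 4 samples. That spread may be technical or a real change of the difference from 24 h to 48 h. They do not cover the spread between repeated cultures, since each group was 1 library. Leaving out a library leaves no residual degrees of freedom with a time term, so these fits had no time term. Their spread came from the group that kept both libraries, so the change from 24 h to 48 h in that group counted as spread. They compare with the 706 and 815 of all libraries. They gave 10 and 18 without the NT library at 48 h, 117 and 247 without the NT library at 24 h, and 3252 and 3474 without the P8i-3 library at 24 h.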

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

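No test in this part was chosen after the result was seen, and the genes were found by comparing the sign of each named gene's difference at both times. Of 143 named genes, 3 stood on opposite sides of the control at 24 h and 48 h beyond their counting intervals, with 1 library per group, and the difference between the times was not tested. BCL2L1, whose main product opposes apoptosis, had log2 differences of -0.16 at 24 h and 0.52 at 48 h, 0.68 apart. BIRC5, which encodes survivin, had 0.08 and -0.21, which differ by -0.29. SNAI2, a transcription factor of mesenchymal cells, had -0.43 and 0.80, which differ by 1.24. None of the 3 passed the edgeR test over both times (adjusted p 0.367, 0.942 and 0.711).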

How the results depend on the processing

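The test of the knockdown compared P8i-3 with NT within each time, with the time label as the block. With 1 library per group there were no replicates to pair within a time. The GC trend removal and the matching on GC content and exon number were chosen after seeing the data; the other alternatives were planned. With a pseudocount of 0.1, counts were 360 higher and 593 lower at 24 h, 953 higher at 48 h, 193 and 128 between the NT libraries, and 226 and 427 at both times. With a mean of at least 5 CPM, which tests 11699 genes, they were 52 and 171 at 24 h, 329 higher at 48 h, 23 and 20 between NT libraries, and 40 higher at both times. Protein-coding genes alone, 13395, gave 61 higher and 246 lower at 24 h, 365 higher at 48 h and 43 higher at both times. Between NT libraries they gave 42 higher and 17 lower. A size of 1.5-fold gave 745 and 1496 at 24 h, 2000 and 3362 at 48 h, 438 and 221 between NT libraries, and 530 and 1200 at both times. With the GC trend removed, 172 were lower at 24 h and 126 at both times. Every count under these settings stayed larger for P8i-3 against NT than between the NT libraries. For protein-coding genes that were higher the margin was small, 61 at 24 h and 43 at both times against 42. The test of the knockdown gave 706 and 815 genes without a time term, of which all 1521 were among the main 3684, and 864 and 1255 with DESeq2, of which 2118 were. Leaving out each library gave 10 to 3252 genes that rose and 18 to 3474 that fell, from a model without the time term in which a lone library is assumed to vary like the others; the cause was not tested. Median ratio scaling and no filter moved the counts by size and the counts of all genes in the test by less than 1.5 times, but not all list counts. Among the list counts that moved more with median ratio scaling, ribosomal protein genes that rose went from 9 to 3 and cholesterol genes that fell from 3 to 1. With no filter, G2 and mitosis genes that fell went from 4 to 7, and SR and hnRNP genes that fell from 2 to 4. The correlation across genes ranged from 0.68 to 0.80 (Pearson). Of 143 named genes, 114 kept direction and side of the threshold with DESeq2 and 24 no longer passed, 134 and 9 with median ratio scaling, and 99 and 44 without a time term; none reversed. The 50 medians of lists with at least 5 members stayed within their bootstrap intervals with a pseudocount of 0.1 and with median ratio scaling. Lists outside the central 95% numbered 8 to 10 at 24 h and 10 to 12 at 48 h, the lowest at 48 h with random lists also matched on GC content and exon number. The planned pseudocount for the test applied to normalized values and was not run. At these totals, genes under 0.101 to 0.106 CPM can stay undetected.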

Other observations

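The long non-coding genes and their counts below, the thinning test, the comparison of GC slopes between genes with few and with many exons, the difference between short genes outside genes and on the host strand, and the list of REST targets were chosen after the result was seen; the other tests were set out before the values they measure. Of 1574 long non-coding genes tested, 38 were higher and 25 lower by at least 1 at 24 h, 158 and 63 at 48 h, and 187 rose and 88 fell over both times (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). MIR34AHG, the host of the p53-induced microRNA miR-34a, rose (log2 1.45, adjusted p = 0.000463), from 13.3 CPM in NT to 49.9 CPM in P8i-3 cells at 48 h. LINC02334 (1.82) and NEAT1 (0.96), the scaffold of paraspeckles, also rose. ESRG, a long non-coding RNA abundant in pluripotent cells, fell (-0.83), from 1657 CPM in NT to 805 CPM in P8i-3 cells at 48 h. MIAT (-1.14) and PWAR6 (-1.36) also fell, and MALAT1 did not pass (-0.30). These genes were named after their values were seen, and the counts rest on the same 4 libraries as the test of the knockdown, which gave 10 and 18 genes of all types without the NT library at 48 h and the time term.

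Genes lower in P8i-3 cells at 48 h were rich in G and C, and a GC-dependent bias of the library would give genes the same slope whatever their exon number. The slope of the log2 difference per 10 points of GC was -0.0412 in 215 single-exon genes (95% bootstrap interval -0.126 to 0.0471) and -0.140 in multi-exon genes, an interval too wide to decide alone. It was -0.0251 (-0.0521 to 0.00205) in genes with 2 to 5 exons against -0.243 (-0.268 to -0.218) with at least 16, and at 24 h -0.101 (-0.116 to -0.0859) against -0.191 (-0.206 to -0.177), which argues against such a bias as the whole cause. At 24 h the single-exon slope (-0.134, -0.197 to -0.0800) was near the multi-exon one (-0.150), and a bias as part of the cause stays open. Within 5 classes of GC content of equal size, genes with at least 16 exons lay lower than genes with 2 to 5 by a mean of -0.414 (-0.454 to -0.379), in 5 of 5 classes, as a dependence on intron number would give. Short introns came with higher values in all but the class richest in GC, with a mean of 0.0895 over all 5 classes. In that class, where 20.9% of genes were lower by at least 1 at 48 h, short introns came with lower values (-0.215). The lower genes also had shorter introns, with a median of 1307 bases against 1829. A part for short introns among the genes richest in GC thus stays open. A loss of long transcripts was not decided (mean Spearman correlation with length at equal exon number -0.0163). These tests suggest, as a hypothesis, that RNA with many introns may be reduced when PRPF8 is low, and spliced reads would be needed to test it.

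The P8i-3 library at 48 h had 27859 genes above 0, against 29381 in NT at 48 h. Its lower total does not account for this, since the NT library thinned to the same total kept 29294. Among genes with 1 to 5 counts in both NT libraries, the share at 0 was 13.8 percentage points higher in this library than in P8i-3 cells at 24 h, 8.88 points among protein-coding genes and 15.3 among others. Only genes with few counts can drop to 0, so this share restates the smaller number of genes and decides nothing. A loss of rare molecules in library preparation and a real loss of rare transcripts in the cells cannot be told apart with these values.

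Short non-coding genes took a larger share of the counts in P8i-3 cells, which could come from reads of retained introns. Short non-coding genes and processed pseudogenes inside introns on the strand of the host gene had a median log2 difference 0.290 above those on the other strand at 48 h (95% bootstrap interval -0.00106 to 0.521) and 0.156 at 24 h (-0.0514 to 0.425). Both intervals reach 0, the limit set beforehand for giving this up. That limit was too strict, because the interval at 48 h extends to 0.521. The strand setting used in counting is also not given, and counts made without regard to strand would raise both strands alike. Genes inside introns on the other strand were also higher at 48 h, by a median of 0.749. The comparison of strands therefore cannot decide for or against intron reads. Short non-coding genes outside protein-coding genes were also higher, by a median of 0.768 (0.586 to 1.04) against 1.10 on the host strand. The difference of -0.328 (-0.672 to 0.0230) leaves open whether they were higher by as much, so a general rise of short RNA cannot be told apart from a rise that is larger inside introns.

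SYT4, VGF and NEFH, neuronal genes that rose, are known targets of the repressor REST, and a shared release of REST targets may be a candidate explanation. The other 27 measured REST targets had a median log2 difference of -0.12 at 48 h, at percentile 47.9 of random lists matched on expression, with 2 members higher and 7 lower by at least 1, which argues against it.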
